A study of Mus musculus with 8 samples.

How the data were processed

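RNA from the brains of 8 male mice on a mixed SJL/Bl6 background was profiled by RNA sequencing. Per the labels, 5 mice carried a bacterial artificial chromosome (BAC, a large cloned piece of genomic DNA) with the human C9ORF72 gene and 500 copies of the G4C2 hexanucleotide repeat, and 3 mice were wild-type. The transgenic mice are called C9-BAC here. Per the labels' protocols, RNA was extracted with Trizol and strand-specific libraries were made from total RNA without selection for poly(A), so that RNAs without a poly(A) tail can be present. The labels name no brain region, age or batch, and each sample is taken as 1 mouse because each has its own number; if samples were drawn otherwise, the p-values measure only the spread between these samples, which can be technical. Replicate numbers are not shared between the genotypes, so no pairing applied.

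The deposited values are the authors' own comparison of both genotypes. Trimmomatic, Bowtie2, DESeq and DESeq2 are named, with build mm10 and no versions, per the submitters' processing notes. The read counter, the gene annotation and the filters are not given in the sources used here. The table has 15978 rows named by RefSeq transcript accessions, in most cases those of a single gene; 20 rows share a symbol with another row and 2 hold more than 1 reference gene. Its 6 columns are those of a DESeq2 result, per the file headers. The mean normalized count is the authors' mean over the samples of counts divided by size factors, a signal that is never negative and not a count per sample. The log2 fold change and its standard error are on the log2 scale, per the file headers. The Wald statistic, a score, is the deposited log2 fold change divided by its standard error, and both the p-value and the adjusted p-value were deposited by the authors. These relations were checked on every row: the deposited statistic differed from the ratio by at most 8.3e-07, the p from the two-sided normal p by at most 8.8e-10, and the adjusted p from a Benjamini-Hochberg (BH) adjustment over the 15944 rows with a p by at most 5.3e-12.

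The file headers do not say which genotype is the numerator of the fold change, and no row of the table settles it. Signs are therefore given as deposited, positive or negative, and never as higher or lower in one genotype. The standard errors fell toward low counts, with a median of 0.0516 for rows with a mean normalized count under 10 and a highest value of 0.11 anywhere. Standard errors of this form arise where fold changes are pulled toward 0 by a prior, a step that no source used here records. With such a prior, deposited fold changes understate differences, most of all for genes with few or variable counts, and a small standard error is no sign of a precise estimate for such genes. The table gives 1 value per gene for the whole comparison, so the depth of each sample, the spread between mice, fits without 1 mouse, other splits of the mice and an inter-gene correlation estimated from samples were not analysed here. The design fixed for this case takes the authors' fold changes and adjusted p-values as the main result. The mean normalized counts sum to 9226666 over all rows, which is the only measure of depth in the table.

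Gene symbols were taken from RefSeq accessions of a GRCm38.p6 gene table for 15857 rows and from GENCODE vM21 transcripts for 73 more, leaving 48 rows without a symbol. GRCm38 is the assembly also called mm10. Of 84 coordinates written into row names that had a reference gene, 82 lay on the same chromosome as the reference gene. Coordinates are 1-based gene bounds from the reference, and those of extra gene copies are as written in the row names. Transcript GC content and length came from the vM21 transcripts and were found for 15869 rows, 99.3% of the table.

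Before the data were examined, 39 gene lists, the tests and the rule for named genes were fixed. The rule names the mouse C9orf72 gene, every gene that passes if 30 or fewer pass, and, if fewer than 20 pass, the genes of smallest unadjusted p with a mean normalized count of at least 10 up to 25 genes. In each list described, it names the 2 members with the smallest p and up to 4 that pass when adjusted over the list alone. Some genes that the rule names are not reported here. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistic, two-sided, with the inter-gene correlation preset at 0.01, over 13704 rows with a p and a mean normalized count of at least 10. Adjusted p-values of lists are BH over the 37 lists with at least 5 such members. The shift of a list is the mean statistic of its members minus that of all other rows. Beside it stands the percentile of the list's median log2 fold change among 10000 random lists of the same size matched on mean normalized count in 20 bins. Lists overlap in some members. Neighbouring rows along chromosomes were tested with a one-sided permutation test of 100000 resamples over 15882 rows with a position and a p. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

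Alternatives to the calls of genes were thresholds of 0.1 and 0.01 on the adjusted p, BH over every row with a p, BH over rows with mean normalized counts of at least 10 and 50, an empirical null (the statistic rescaled by its median and its SD from the median absolute deviation, MAD), and a minimum absolute log2 fold change of 0.5. Alternatives to the list test were log2 fold changes, ranks, a preset correlation of 0.05, a minimum mean normalized count of 50, no minimum, and residuals on mean expression. Residuals on GC content and length, rows without a p kept in, and an empirical null after the median statistic of each of 20 GC bins was taken off were added after the data were seen. The fits listed for tables with values per sample were not run.

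The gene calls, the list test and the test of neighbouring rows were tested on simulated data. With 200 of 15944 simulated statistics shifted by 5, BH recovered 93.7% of the shifted genes at a null SD of 1 and 97.2% at a null SD of 0.8. At a shift of 3 these shares were 20.6% and 11.2%. In 50 simulations over 13704 rows, 86.5% of lists shifted by 0.8 SD were called and 9.8% of lists shifted by 0.4 SD, with 0.28% and 0.21% of the unshifted lists. Simulated genes were drawn independently, so the shares of unshifted lists called do not carry over to lists whose genes vary together. The chromosome test called 100% of 20 simulations with 3 planted neighbouring pairs and 0% of those without. At the p level fixed beforehand, permuted orders of the real rows gave a mean of 0.017 pairs and at most 2. Planted pairs that all pass that level are therefore called almost by construction. The 100% does not measure how well weaker pairs in these data would be found.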

Results

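Brain RNA was compared between 5 male C9-BAC mice, which carried the human C9ORF72 gene with 500 G4C2 repeats, and 3 male wild-type mice. Expansion of this repeat in C9ORF72 is a known cause of amyotrophic lateral sclerosis (ALS) and frontotemporal dementia (FTD). The comparison asks how the transgene with its repeats alters the brain transcriptome. The authors' deposited table holds 15978 rows, with mean normalized counts from 1.02 to 149771 and a median of 170.8. Among the most abundant rows in the authors' deposited table were the nuclear RNA Malat1 (149771), the astrocyte glutamate transporter gene Slc1a2 (45838.8), the kinesin gene Kif5a (31412.2) and the imprinted RNA Meg3 (27855). Genes of the cerebral cortex and striatum were well represented: 19 of 22 cortical list genes and 18 of 23 striatal list genes had a mean normalized count of at least 100 in the authors' deposited table, against 2 of 14 for the hypothalamus and 6 of 19 for the cerebellum. The olfactory bulb (9 of 20), thalamus (8 of 19) and hippocampus (6 of 18) lay between.

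No gene changed between C9-BAC and wild-type brain at a DESeq2 adjusted p of 0.05, and 239 had an unadjusted p under 0.05 in the authors' deposited table. In the authors' deposited table the fold changes, from DESeq2, ran from 0.802 to 1.27, and 82.6% of rows had a log2 fold change within 0.1 of 0. No standard error was above 0.11, a form that arises where a prior pulls fold changes toward 0. If a prior was used, these fold changes understate the differences and set no upper bound on them. The smallest p belonged to Lamp5, a membrane protein gene of certain cortical and other neurons, on chromosome 2 at 136052025 to 136069917 (mm10), with a log2 fold change of 0.35 and a standard error of 0.10 in the authors' deposited table (p = 0.000714, DESeq2 adjusted p = 0.9997). Mouse C9orf72, on chromosome 4 at 35191285 to 35226153, had a mean normalized count of 311.2 and a log2 fold change of -0.08 with a standard error of 0.10 in the authors' deposited table (p = 0.454, DESeq2 adjusted p = 0.9997). A row for the human transgene was not used here. Which genotype is the numerator is not stated, so every sign below is as deposited.

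The adjusted p-values from DESeq2 in the authors' deposited table lay between 0.9997 and 0.99998, and 239 of 15944 rows (1.499%, 95% Wilson interval 1.32 to 1.70) had an unadjusted p under 0.05, 105 of them positive and 134 negative. A share of 5% is what no difference at all would give if the statistic followed a standard normal. Its MAD-based SD was 0.777 where a standard normal has 1, so a share under 5% can reflect p-values that are too large. Rescaled to the empirical null, 679 of 13704 rows with a mean normalized count of at least 10 (4.95%) were under 0.05. The rescaling itself brings the share near 5%. The Wilson interval counts rows as independent and does not measure the spread between mice. An unadjusted p under 0.01 was reached by 25 rows. A single call would have needed a p of 3.14e-06, which is a statistic of 4.662, and the largest absolute statistic in the authors' deposited table was 3.384. At the median standard error of 0.102 the statistic needed corresponds to a log2 fold change of 0.475, or 1.39-fold on the deposited scale. The share of unchanged genes, estimated from the p-values over 0.5, came out at 1.229, above its ceiling of 1, because 61.5% of rows had a p over 0.5. With the statistic rescaled to an empirical null after its trend with GC content was taken off, a setting chosen after the data were seen, 2 genes passed, Lamp5 (adjusted p = 0.0153) and Mical2 (adjusted p = 0.023).

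**Figure D1:**
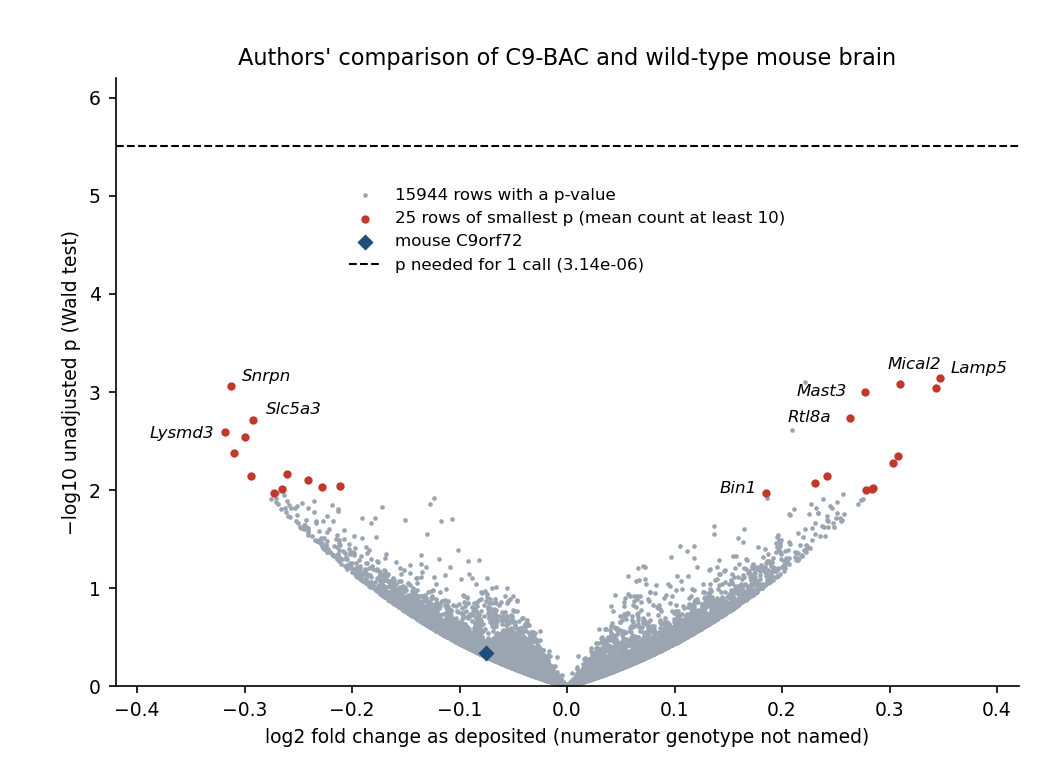
Log2 fold change as deposited (x axis) against −log10 of the unadjusted p (y axis) for the 15944 rows with a p-value. Red points are the 25 named rows of smallest p, the blue diamond is mouse C9orf72, and the dashed line is the p of 3.14e-06 that a single call would have needed. Every row lies below that line.

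The 25 genes of smallest p comprised 13 with positive and 12 with negative fold changes, with absolute log2 fold changes of 0.18 to 0.35 and standard errors of 0.072 to 0.11 in the authors' deposited table. None passed, and all had a DESeq2 adjusted p of 0.9997. Positive values in the authors' deposited table belonged to Lamp5, to Mical2, a flavoprotein monooxygenase that acts on actin (log2 fold change 0.31, standard error 0.09), to the kinase gene Mast3 (0.28, standard error 0.08), to the axon guidance receptor gene Robo3 (0.31, standard error 0.11), and to Wwc1, also called KIBRA (0.30, standard error 0.11). The authors' deposited table also gave positive values for Rtl8a, Txn2 (mitochondrial thioredoxin), Sema7a (a semaphorin), Myl4 (a myosin light chain), Nol12, Bin1 (a membrane-bending protein), 4933409K07Rik and Fam205a2. Negative values in the authors' deposited table belonged to Lysmd3 (log2 fold change -0.32, standard error 0.11), Snrpn (-0.31, standard error 0.09), the GABA-A receptor subunit gene Gabrg1 (-0.31, standard error 0.11), Prxl2a (-0.30, standard error 0.10) and the myo-inositol transporter gene Slc5a3 (-0.29, standard error 0.09). The other negatives were Tiparp (an ADP-ribosyltransferase), Glrx2 (mitochondrial glutaredoxin), Dhx15 (an RNA helicase of the spliceosome), Zfp397, Etnppl, Psme4 (a proteasome activator) and 4930447C04Rik. The median transcript GC content was 56.5% for the 12 positive genes with a value and 42.5% for the 12 negative ones, against 50.5% for all rows.

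Several of these rows overlap another row or have near-identical copies with which reads can be shared, and are uncertain. The Snrpn row had a mean normalized count of 29.9 in the authors' deposited table and lies on chromosome 7 at 59982495 to 60450177, where it overlaps the Snurf row, with a mean normalized count of 7448 and a log2 fold change of 0.05 in the authors' deposited table. Rtl8a, on chromosome X at 53642488 to 53643763, has near-identical relatives, Rtl8b and Rtl8c, whose p-values in the authors' deposited table were 0.347 and 0.828. The row 4933409K07Rik names a copy on chromosome 4 at 42031295 to 42055130, and Fam205a2 names copies at 42318271 to 42324070 and 42522438 to 42528237 on the same chromosome. How the authors' counting treated reads that fit more than 1 copy is not given in the sources used here.

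Of the 37 gene lists tested, 2 passed cameraPR at an adjusted p of 0.05, and both calls were lost at a preset correlation of 0.05 (adjusted p = 0.191 for each) and after GC content and length were accounted for (adjusted p = 0.0732 for each). A correlation estimated from samples was not used here. The neuronal and synaptic genes shifted to positive values: 25 of 35 had positive and 10 negative fold changes in the authors' deposited table, with a mean shift of the statistic of 0.532 (adjusted p = 0.0219), a median log2 fold change of 0.06 and a percentile of 99.77 among matched random lists. Thy1, a surface glycoprotein of neurons, had a log2 fold change of 0.21 with a standard error of 0.09 in the authors' deposited table, and the syntaxin gene Stx1a one of 0.25 with a standard error of 0.11. The olfactory bulb and neuroblast genes shifted to negative values, 2 positive and 13 negative of 15 in the authors' deposited table, with a mean shift of -0.677 (adjusted p = 0.0357), a median log2 fold change of -0.07 and a percentile of 0.37. Among them Sox11, a transcription factor gene of immature neurons, had a log2 fold change of -0.24 with a standard error of 0.11 in the authors' deposited table, and the prokineticin receptor gene Prokr2 one of -0.16 with a standard error of 0.09. With GC content and length accounted for, a shift of 0.387 was left for the neuronal list and of -0.545 for the olfactory list. The neuronal call was also lost with ranks (adjusted p = 0.057) and residuals on mean expression (adjusted p = 0.111). The olfactory call was lost under every alternative run except no filter on low counts (adjusted p = 0.0526 to 0.191), among them rows without a p kept in (adjusted p = 0.0698), and the standard errors of this list were low for its abundance (median percentile 2.0). No single member of either list passed over all genes or adjusted over the list alone.

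**Figure D2:**
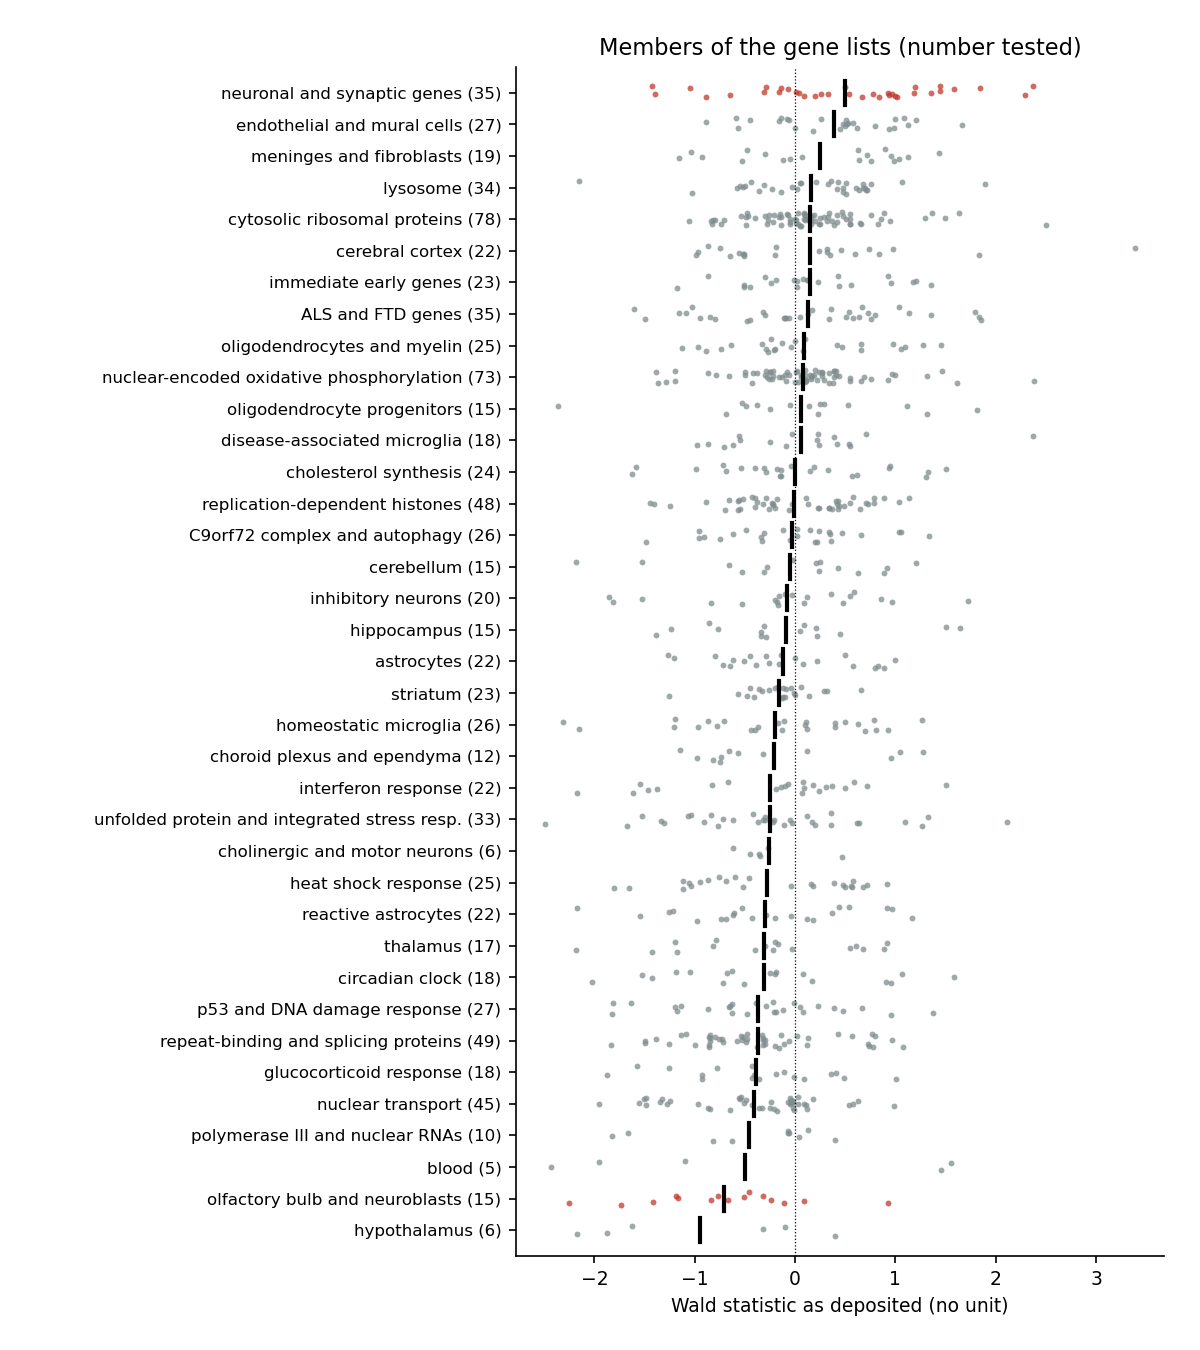
Wald statistic as deposited (x axis) of each tested member of the 37 gene lists (y axis, number of members in brackets), ordered by mean shift, with the mean of each list as a black bar. The lists in red passed cameraPR: neuronal and synaptic genes with a shift of 0.532 and olfactory bulb and neuroblasts with -0.677. Vertical scatter within a list carries no value.

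The statistic was higher at higher transcript GC content across the table. Its median went from -0.547 in the fifth of rows with the lowest GC content to 0.352 in the fifth with the highest, and the share of positive rows from 21.7% to 69.2%. Across 13627 genes, which are not independent replicates, Spearman's rho with GC content was 0.414 and Pearson's r 0.405, and with transcript length rho was -0.11. The lists differed in GC content, though not in the order of their shifts: the median was 54.5% for the neuronal and synaptic genes, 49.0% for the olfactory bulb genes, 47.6% for the nuclear transport genes, 44.1% for the splicing genes and 52.2% for the endothelial genes.

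**Figure D3:**
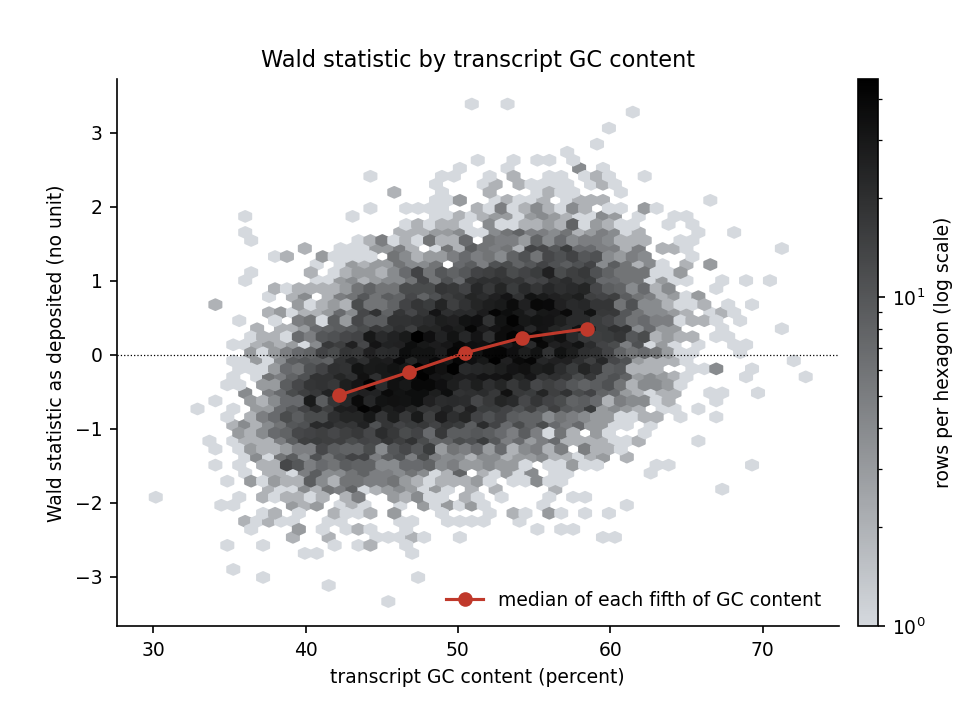
Wald statistic as deposited (y axis) against transcript GC content in percent (x axis) for 13627 rows with a mean normalized count of at least 10, shaded by rows per hexagon on a log scale. Red points are the medians of 5 equal groups of rows by GC content, from -0.547 to 0.352.

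Further groups came next in order and did not pass. Hypothalamic genes had 1 positive and 5 negative members and a mean shift of -0.917 (cameraPR adjusted p = 0.0692). This list was called without a filter on low counts (adjusted p = 0.00823) and after GC content and length were accounted for (adjusted p = 0.00849), but not at a preset correlation of 0.05 (adjusted p = 0.191) or with ranks (adjusted p = 0.301). Its 2 members of smallest p, Baiap3 and Peg10, had log2 fold changes of -0.20 and -0.19 with standard errors of 0.09 and 0.10 in the authors' deposited table. Nuclear transport genes had 10 positive and 35 negative members (shift -0.373, adjusted p = 0.0794), with Nup160, a nuclear pore gene, at -0.20 and the nucleoporin gene Ranbp2 at -0.16 on the log2 scale in the authors' deposited table. Repeat-binding and splicing proteins had 12 positive and 37 negative members (shift -0.34, adjusted p = 0.0843, percentile 0.05 among lists not matched on GC content), led in the authors' deposited table by Purb at -0.19 and Hnrnpd at -0.16. With GC content and length accounted for, the shifts were -0.0681 for the splicing list (adjusted p = 0.721) and -0.243 for nuclear transport (adjusted p = 0.272). Endothelial and mural cell genes had 19 positive and 8 negative members (shift 0.422, adjusted p = 0.0843, percentile 99.86), led in the authors' deposited table by Pecam1 at 0.17 and Myh11 at 0.13.

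The C9orf72 complex and the lists of ALS and FTD genes and lysosomal genes did not pass either. The 26 genes of the C9orf72 complex and autophagy had a mean shift of 0.001 (adjusted p = 0.996), 14 positive and 12 negative, with Rab39b at a log2 fold change of -0.15 and Atg13 at 0.12 in the authors' deposited table. ALS and FTD genes had 19 positive and 16 negative members (shift 0.16, adjusted p = 0.54), and Sod1 and Anxa11 had log2 fold changes of 0.20 and 0.19, each with a standard error of 0.11, in the authors' deposited table. Lysosomal genes had 22 positive and 12 negative members (shift 0.194, adjusted p = 0.442, percentile 98.22), with Mcoln1 at 0.17 in the authors' deposited table. None of the members of these lists passed.

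Stress and immune groups did not pass either. The unfolded protein and integrated stress response had 11 positive and 22 negative members (shift -0.221, adjusted p = 0.411), and its genes Edem1 and Hyou1 had log2 fold changes of -0.26 and 0.20 in the authors' deposited table. The heat shock response had a shift of -0.244 (adjusted p = 0.411), with Dnaja1 at -0.17 and Hsf2 at -0.18 in the authors' deposited table, and the p53 and DNA damage response a shift of -0.333 (adjusted p = 0.274), with Trp53inp1 at -0.19 and Fas at -0.15. The interferon response had 11 positive and 11 negative members (shift -0.219, adjusted p = 0.465) and a median log2 fold change above 0, opposite in sign to its mean, with H2-D1 at -0.24 and Ifit2 at -0.18 in the authors' deposited table. Homeostatic microglia genes had a shift of -0.162 (adjusted p = 0.543), with Gpr34 at -0.25 in the authors' deposited table, and disease-associated microglia genes a shift of 0.088 (adjusted p = 0.79), with Fth1 at 0.21 and Lyz2 at -0.11. The shifts of reactive astrocytes (-0.268), astrocytes (-0.083), immediate early genes (0.181) and the glucocorticoid response (-0.352) did not pass.

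Among markers of cell types and regions, the cerebral cortex list held the 1 gene that passed when adjusted over the list alone, Lamp5 (adjusted p = 0.0157), while the list itself had 11 positive and 11 negative members (shift 0.186, cameraPR adjusted p = 0.54). The next cortical gene, Ccn2, had a log2 fold change of 0.20 with a standard error of 0.11 in the authors' deposited table. Striatal genes had 5 positive and 18 negative members (shift -0.125, adjusted p = 0.653), led by Strip2 at -0.11 and Foxp1 at 0.07 in the authors' deposited table. The lists for thalamus (-0.277), hippocampus (-0.057), cerebellum (-0.016), inhibitory neurons (-0.051), cholinergic and motor neurons (-0.227), oligodendrocytes (0.121), oligodendrocyte progenitors (0.095), meninges (0.28), choroid plexus (-0.18) and blood (-0.464) had shifts that did not pass. Cytosolic ribosomal proteins (0.189), nuclear-encoded oxidative phosphorylation (0.114), replication-dependent histones (0.023), polymerase III and other nuclear RNAs (-0.425), cholesterol synthesis (0.037) and the circadian clock (-0.28) did not pass either. Pituitary genes, with 4 in the table, and mitochondrial genome genes, with 0, were not tested.

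At the level fixed beforehand, genes with low p gave no neighbouring pairs on the chromosomes that shared a direction. Permuted orders gave almost none either, so this count says little. Of 24 placed rows with an unadjusted p under 0.01, 0 neighbouring pairs shared a direction, against a mean of 0.017 in permuted orders (permutation p = 1.0, one-sided). At an unadjusted p under 0.05 there were 5 such pairs among 235 rows, against a mean of 1.75 (permutation p = 0.0317). These were Misp with E130317F20Rik on chromosome 10, Ranbp17 with Kcnip1 on chromosome 11, the zinc finger genes Zfp944 and Zfp758 on chromosome 17, Zfp579 with Fiz1 on chromosome 7, and Sox1 with its overlapping transcript Sox1ot on chromosome 8. All were negative in the authors' deposited table except Zfp579 and Fiz1, which had log2 fold changes of 0.22 and 0.20. The permutation treats rows as independent, which overlapping rows such as Sox1 and Sox1ot need not be. Leaving out related or overlapping pairs was not run at this threshold, so the permutation p can be too small.

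The size of the standard error differed between kinds of genes of like abundance. In the authors' deposited table the haemoglobin gene Hba-a2, with a mean normalized count of 1183, had a standard error of 0.043, and the striatal receptor gene Adora2a, at 338.6, one of 0.041, while the median over all rows was 0.102. By abundance, the median standard error in the authors' deposited table was 0.0516 under a mean normalized count of 10, 0.1088 from 50 to 200 and 0.0961 at 2000 or more. For 34 genes, among them Hba-a2, Fosb and Nptx2, the authors' deposited table gives a fold change without a p-value. These were left out of the gene calls, the main list test and the test of neighbouring rows.

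**Figure D4:**
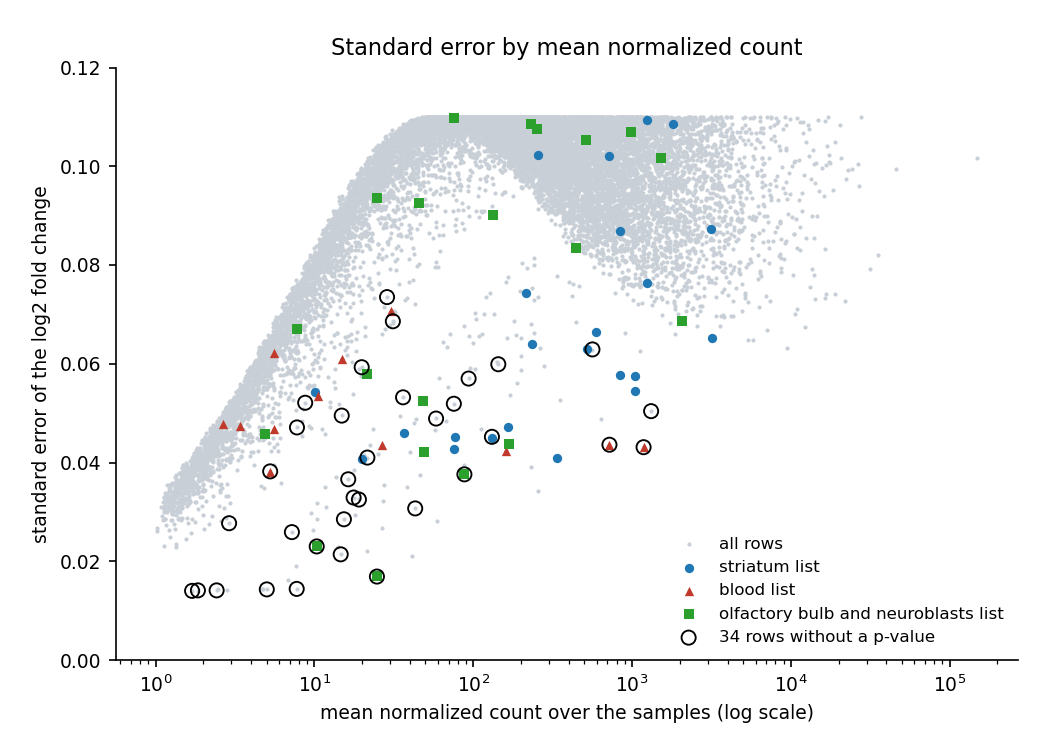
Standard error of the log2 fold change (y axis) against mean normalized count on a log scale (x axis) for all 15978 rows, with the striatum, blood and olfactory bulb lists coloured and the 34 rows without a p-value circled. Most rows follow a band that reaches 0.11, and many striatal and blood genes and all circled rows lie below it.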

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

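Settings that account for GC content, and the one that keeps rows without a p, were chosen after the data were seen. The number of changed genes was 0 at an adjusted p threshold of 0.1, with BH over rows with mean normalized counts of at least 10 or 50, and with an empirical null, under which the lowest adjusted p was 0.0809 (Lamp5). A threshold of 0.01 and a minimum log2 fold change of 0.5 can only remove calls, and BH over all rows equals the deposited adjustment, so these settings test nothing here. With the GC trend taken off as well, 2 genes passed: Lamp5 (adjusted p = 0.0153) and Mical2 (adjusted p = 0.023). This alternative narrows the null (MAD-based SD 0.681 against 0.789), and no other cause was tested. The 2 called lists became 1 with log2 fold changes, 1 at a mean normalized count of at least 50 and 1 with rows without a p kept in, each time the neuronal and synaptic genes. The number was 0 with ranks, 0 at a preset correlation of 0.05 and 0 with residuals on mean expression, and 1, the hypothalamus, with residuals on GC content and length; without a filter it was 3. The cause was not tested. Adjusted p-values over these alternatives ran from 0.00823 to 0.191 for both lists. Adjusting over each list alone moved the members that passed from 0 to 1, since fewer genes are then tested. Pairs of neighbouring low-p genes went from 0 to 5 at an unadjusted p under 0.05 (permutation p = 0.0317), and to 5 with the GC trend taken off too (permutation p = 0.00149); the cause was not tested. The share of rows with p under 0.05 stayed within its interval at 1.63% and 1.65% under both count minimums. These settings keep 223 and 186 of the same 239 rows, so a similar share was nearly given beforehand. Fits by other tools or pseudocounts, leaving out single mice and other splits of the 8 mice need values per sample and were not run, so how far 1 mouse decides any value is open.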

Other observations

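The tests of rows without a p-value, of standard errors, of the block on chromosome 4 and of transcript length were chosen after the patterns were seen, on gene lists fixed beforehand.

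The rows for which the authors' deposited table gives no p-value, 34 in all, held genes of 7 fixed lists more often than the whole table did. They included 15 genes of the fixed lists, where 2.13 were expected from all rows. Blood genes among them were the haemoglobin genes Hba-a2 and Hbb-bs and the platelet chemokine gene Ppbp (Fisher's exact test, one-sided, BH over 38 lists, adjusted p = 7.26e-05). Olfactory bulb genes were Doc2g and the transcription factor genes Eomes and Tbx21 (Fisher's exact test, adjusted p = 0.000186), and cholinergic genes were Ngfr and the choline transporter gene Slc5a7 (Fisher's exact test, adjusted p = 0.00303). The other lists were the hypothalamus with Lhx8 and Oxt (adjusted p = 0.00374 by Fisher's exact test), the glucocorticoid response with Cdkn1a and Lcn2 (0.0062), immediate early genes with Fosb and Nptx2 (0.0081) and the pituitary with Gh (0.0461). Blanks of this kind are DESeq2's mark for a gene in which a single sample has an extreme count. Whether that holds here cannot be read from pooled values. Fisher's exact test counts genes as independent, while genes of a list can go blank together through a single sample. If that happened, the p-values above are too small.

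Striatal genes stood apart by their standard errors, and their deposited fold changes lay near 0. If a prior pulled them there, values near 0 do not show that striatal genes were unchanged. Among the 201 rows closest in mean normalized count, the median striatal gene lay at percentile 0.5 of the standard error, and 16 of 23 lay under percentile 5 (10000 random lists, adjusted p = 0.00106, from the smallest p these can give). Genes of a list can vary together through a single sample, which random lists do not carry. The adjusted p-values from random lists in this paragraph can therefore be too small and do not measure the spread between mice. The adenosine receptor gene Adora2a had a log2 fold change of 0.0023 with a standard error of 0.041 in the authors' deposited table, the dopamine receptor gene Drd2 one of 0.0063 with a standard error of 0.045, and Penk, the enkephalin precursor gene, one of -0.0067 with a standard error of 0.054. Olfactory bulb genes (percentile 2.0), cholinergic genes (1.0), blood genes (1.5), hypothalamic genes (2.5), replication-dependent histones (12.5) and immediate early genes (16.5) had the same adjusted p, choroid plexus genes lay at 9.2 (adjusted p = 0.00247), and the 34 rows without a p-value had a median percentile of 0.5. Circadian clock genes (percentile 80.2, adjusted p = 0.00666), ribosomal protein genes (68.8, adjusted p = 0.00185) and oxidative phosphorylation genes (65.0, adjusted p = 0.0316) lay on the other side. In a fit with a prior on fold changes, a small standard error belongs to precisely measured genes or to genes with few or variable counts. Rows under a mean normalized count of 10 had a median standard error of 0.0516, against 0.0961 at 2000 or more. This argues against precision as the source of small standard errors in those low-count rows. For the striatal and other lists, precision and variation between samples were not told apart here. No source used here records whether such a fit was made.

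The rise of the statistic with GC content and the list calls were weighed together. Within 337 genes of 7 widely expressed lists, among them ribosomal proteins, oxidative phosphorylation and nuclear transport, rho between statistic and GC content was 0.492, as a GC-dependent difference between the libraries of both genotypes would give; transcript length in its place is argued against, since rho stayed at 0.387 with the length trend taken off. For the neuronal and olfactory calls, accounting for GC content and length left 0.771 of the median shift (0.604 before, 0.466 after) while ending both calls, so the trend is not shown to be their whole source, nor is it excluded. A difference between the genotypes, or in which parts of the brain were dissected, stays open and was not tested. The GC trend may thus be technical, as a hypothesis.

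The narrow spread of the statistic was the second pattern weighed. Genes with low counts are argued against as its source, because the MAD-based SD was 0.79 (bootstrap interval 0.762 to 0.814) among 4248 rows with a mean normalized count of at least 500, where a standard normal has 1. Library differences along GC content that enter the dispersions stay open: the standard error was higher away from the median GC content (Spearman's rho 0.194 across 4244 genes, bootstrap interval 0.166 to 0.223), but standard errors in this table also fall where there is less information, so that their direction does not show which genes vary more. The prior on the fold changes and unlike dissections of single brains were not tested.

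The hypothesis that segments of the mixed background group low-p genes along chromosomes was fixed beforehand and gave 0 pairs at p under 0.01. With a permuted mean of 0.017 that count leaves no room below chance. The 5 pairs at p under 0.05 include the overlapping rows Sox1 and Sox1ot, so they leave segregating segments open without favouring them. A block of 7 rows between 42031295 and 42665763 on chromosome 4, most with more than 1 genomic copy, had positive log2 fold changes in the authors' deposited table: 4933409K07Rik 0.34, Fam205a2 0.28, Ccl27b 0.19, Gm3893 0.10, Gm21953 0.09, Gm2002 0.04 and Gm13304 0.04, with standard errors of 0.0282 to 0.108. The block was picked for these values, so they are not independent evidence of a difference there. The 40 other rows within 1 Mb had a median statistic of 0.274 of the block's (bootstrap interval 0.104 to 0.467) and 32 of them were positive, which leaves a segment that differs as a whole open. Reads or copies shared among rows remain possible: 58.3% of 36 pairs of other multi-copy rows within 1 Mb shared a sign.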
